A study of Lactuca sativa with 17 samples.

How the data were processed

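RNA from lettuce leaves was labelled with Cy5 and hybridized to 1-colour CombiMatrix arrays of 12544 spots, per the labels' protocols. Of these spots 12000 were unigene probes, 148 were blank, 70 were negative controls and the others were quality controls. Each deposited array file holds, per the file headers, the mean, SD and median of the foreground intensity of each spot and a normalized intensity; there is no background column. How the authors normalized is not given in the sources used here. The deposited values show it: the sorted normalized intensities are identical on all 17 arrays, and on 15 arrays they rank the spots as the median foreground does (rank correlation at least 0.9998), which is what quantile normalization of the median foreground with no background correction gives. The authors' deposited value table of the series holds these same normalized intensities, with a largest difference of 0.

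The foreground columns of 2 arrays are copies. Those of PAA day 3 replicate 1 equal those of SH day 3 replicate 1 in every spot, and those of SH day 1 replicate 1 equal those of SH day 1 replicate 2. The normalized intensities of these arrays differ from their partners' (r = 0.972 and 0.966 on the log2 scale) and from their own foreground columns (rank correlation 0.971 and 0.961). All 17 arrays were therefore analysed from the normalized column, and each counts as a separate array. Alternatives that start from the foreground (normexp by negative controls, median scaling, cyclic loess) were run only on the 15 arrays with their own foreground columns, with quantile normalization of the same 15 arrays beside them.

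Normalized intensities of the 12000 unigene probes were taken to log2 with no pseudocount or filter. Control spots were left out of the tests. Each probe has 1 spot. limma 3.58.1 in R 4.3.3 fitted 6 group means to all 17 arrays (lmFit, contrasts.fit, eBayes), so that all groups share an estimate of the spread, and probes with a Benjamini-Hochberg adjusted p under 0.05 were counted by direction. Every adjusted p in the text is from limma. The average sanitizer effect weights the 3 days equally. The interaction is the moderated F-test of the changes in the sanitizer effect from day 1 to days 3 and 6. The comparisons, the test, the rule for named probes and most alternatives were fixed before the data were examined; alternatives chosen after seeing the data are named as such. Named probes are the 2 highest and 2 lowest by log2 difference among called probes whose arrays do not overlap between the groups (for the average, with 1 sign on all 3 days); every called probe of a single-day or storage comparison met that condition, which chance meets for 10% of probes with 3 arrays against 3. Of the probes picked by this rule, 2 are not reported here. For the interaction all 5 called probes are named, 3 of which (TC25063, TC19069 and TC19664) that rule did not pick and were chosen after their values were seen.

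A probe at the scanner's ceiling (65535) on every array of a group has only a bound there, and its fold is given as at least the measured one, from means of normalized log2 values; for the 2 arrays with copied columns saturation is unknown. The files hold no mark for background, so a probe was taken as well above it where it exceeded the 95th percentile of the negative controls, a cut chosen after seeing the data. Where a probe did so on no array of a group, the fold is at least the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest unigene signal above that cut and the probe's own. No fold is given where this is under 1. These bounds allow for saturation and background only, and not for the spread between arrays or for other processing. The log2 differences printed for probes with a bound are those of the measured values. In the order of the figure, the dimmer group (for the average, that of any day) was so for 30 of 47, 58 of 87, 14 of 21, 132 of 178, 19 of 38, 7 of 10, 11 of 32 and 11 of 30 called probes. No group compared was well above background for 10, 19, 7, 46, 6, 1, 3 and 2 of them. On each array 93.1% to 100.0% of unigene probes were brighter than the 95th percentile of the blank spots, and 30.5% to 49.0% were brighter than that of the negative controls. On data simulated for 12000 probes with the measured means and spreads, the fit found 35 of 100 probes changed by 1 on the log2 scale and 81 of 100 changed by 2 for the sanitizers on day 3, with 3 false calls. For the average over days it found 75 and 99 of 100, with 9 false calls, and for SH day 3 against day 1 it found 38 and 78 of 100, with 7 false calls. These values were drawn independently for each probe and array, with no ceiling. In the data, 1 component held 57.2% of the variance left after the group means. How many probes are found or falsely called under such a shared deviation was not simulated. Under it, counts of probes with an unadjusted p under 0.05 can lie well above or below the 600 expected by chance. Such a count alone therefore decides nothing about the called probes.

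The 5 arrays of bright control spots (PAA day 3 replicate 3, PAA day 6 replicate 2 and replicate 3 of SH on days 1, 3 and 6) are those above the widest gap in the median normalized intensity of the QC-3prime spots, 59069 or more against 44143 or less. The same 5 arrays stand apart on the first principal component, which holds 41.9% of the variance of log2 intensity. This set was defined after seeing the data. The 29 gene lists fixed beforehand match on gene descriptions, which the tables used here do not hold, so 0 lists could be tested. Figures were drawn with matplotlib 3.10.9.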

Results

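Gene expression was measured in fresh-cut leaves of lettuce (Lactuca sativa) that had been treated with either of 2 sanitizers and then stored. The sanitizers are named PAA and SH in the treatment labels, and the sample titles write STD for SH; none of these abbreviations is spelled out there. Leaves were sampled on storage days 1, 3 and 6. The 6 groups held 17 arrays, with 2 arrays for PAA on day 1 and 3 arrays for each other group. Each array carried 12000 probes, 35 bases long, each for a different lettuce unigene (an assembled transcript with an identifier that starts with TC). The tables used here do not pair these identifiers with gene names, so probes are given by identifier and sequence, with at most 2 that were higher and 2 that were lower per comparison. The number of arrays per group limits the precision of every value. On the 15 arrays with a foreground column of their own, the median probe was 3.12 to 19.4 times as bright as the median blank spot, and 3.41% to 8.13% of probes were at the scanner's ceiling. A probe that exceeded the 95th percentile of the negative control spots on no array of a group was not well above background there, and its fold is given as a bound. Folds given as at least a value do not allow for the spread between arrays, so they are not confidence limits. Nothing in the labels says whether the arrays of a group came from separate lots of leaves, so p-values measure only the spread between these arrays.

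**Figure D1:**
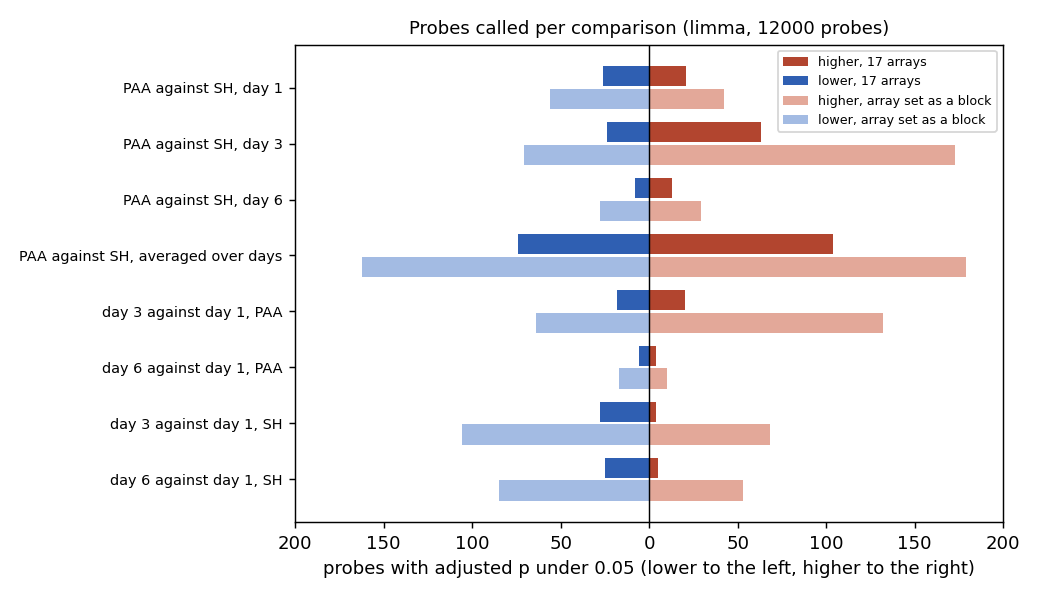
Bars give the number of probes with an adjusted p under 0.05 in each of 8 comparisons, with lower probes to the left and higher probes to the right. Dark bars are the fit of 17 arrays and pale bars are the same fit with a set of 5 arrays with bright control spots as a block; the pale bars are longer in all 8 comparisons, for example 341 against 178 probes for the sanitizers averaged over days.

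The first question was how leaves treated with PAA differed from leaves treated with SH, day by day. On day 1, TC19689 (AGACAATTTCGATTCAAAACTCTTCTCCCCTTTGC) was at least 10-fold lower under PAA, with an adjusted p of 3.8e-05 with limma. It was not well above background under PAA, and under SH its log2 level was 15.96 ± 0.05 (SD, n = 3). There 1 of the 2 arrays with their own foreground was saturated, so the SD can be too tight. TC27339 (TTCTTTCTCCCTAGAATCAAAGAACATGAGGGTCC) was at least 7.88-fold lower under PAA, where it was not well above background. TC25121 (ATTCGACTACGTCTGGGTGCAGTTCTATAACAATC) was at least 7-fold higher under PAA, because it was saturated on both PAA arrays; under SH it was well above background on 2 of 3 arrays. TC27189 (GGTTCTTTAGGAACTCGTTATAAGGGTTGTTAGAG) was at least 1.68-fold higher under PAA (adjusted p 0.0112 with limma) and not well above background under SH. In all, 26 probes were lower and 21 higher under PAA, and 519 probes had an unadjusted p under 0.05 where 600 would be expected by chance. With the 5 arrays of bright control spots as a block the calls were 56 lower and 42 higher, and the 12 arrays outside that set gave 61 and 53; the set holds an SH array and no PAA array of day 1, so no value within it can be had. The count of 47 fell to 20 without PAA replicate 1, to 21 without SH replicate 1 and to 25 without SH replicate 2. Without PAA replicate 2 the split was 30 lower and 6 higher. The 15 arrays with their own foreground split 5 lower and 0 higher with median scaling and 6 lower and 1 higher with cyclic loess. The adjusted p of TC27189 rose to between 0.0644 and 0.126 when either PAA array or SH replicate 1 was left out. Its call also ended in all 4 fits of the 15 arrays, where that of TC25121 ended with median scaling. Normexp by negative controls moved the measured log2 difference of TC27189 from 2.59 to 1.49 and that of TC25121 from 2.81 to 3.56. Median scaling moved that of TC25121 to 2.44.

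On day 3, TC27189 was at least 2.73-fold higher under PAA, at a log2 level of 14.13 ± 0.32 (SD, n = 3), and not well above background under SH. TC22035 (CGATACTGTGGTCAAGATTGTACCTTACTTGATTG) was at least 5.14-fold higher under PAA and likewise not well above background under SH. TC23205 (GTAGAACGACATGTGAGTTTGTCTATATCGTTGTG) was at least 3.37-fold lower under PAA, where it was not well above background; under SH it was so on 2 of 3 arrays. In all, 24 probes were lower and 63 higher under PAA, with 907 probes at an unadjusted p under 0.05 against 600 expected. Blocking on the set of 5 arrays gave 71 lower and 173 higher, and outside the set 47 and 134; the pair of arrays inside it gave log2 differences of 3.01 for TC27189, 1.68 for TC22035 and -2.15 for TC23205. The count of 87 fell to 20 and 28 without PAA replicates 1 and 2, to 26 without SH replicate 1, to 26 without SH replicate 2 and to 50 without SH replicate 3. TC22035 and TC23205 lost their call without any of PAA replicates 1 and 2 and SH replicates 1 and 2, TC22035 also without SH replicate 3 and TC23205 also without PAA replicate 3. In the 15 arrays with their own foreground, the call of TC22035 ended in all 4 fits, that of TC23205 in all but median scaling and that of TC27189 with normexp by negative controls. Normexp moved the measured log2 differences from 3.77 to 2.82 (TC22035), 3.60 to 2.27 (TC27189) and -2.89 to -2.18 (TC23205). That of TC22035 was 4.81 outside the set, 4.39 with arrayWeights and 4.51 without PAA replicate 3. The split of these arrays was 7 lower and 10 higher with quantile normalization, 6 and 7 with median scaling and 7 and 8 with cyclic loess.

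On day 6, TC16126 (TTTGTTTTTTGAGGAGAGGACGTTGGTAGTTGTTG) was lower under PAA by a measured 3.13-fold, at a log2 level of 14.02 ± 0.04 (SD, n = 3) against 15.66 ± 0.11 (SD, n = 3) under SH, where 2 of the 3 arrays were saturated. The fold can therefore be too small. TC27189 was at least 1.85-fold higher under PAA. TC27525 (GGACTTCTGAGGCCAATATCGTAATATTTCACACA) was called higher too (adjusted p 0.00197 with limma), but no fold can be given. Under SH neither was well above background, and under PAA each was on 2 of 3 arrays. In all, 8 probes were lower and 13 higher under PAA, and 282 probes had an unadjusted p under 0.05, against 600 expected by chance. The fit with that set as a block gave 28 lower and 29 higher, and outside the set 19 and 35, where TC16126 had an adjusted p of 0.0619 with limma; the pair of arrays inside gave log2 differences of -1.63 for TC16126, 1.38 for TC27189 and 1.62 for TC27525. The count of 21 was 10, 36 and 5 without PAA replicates 1, 2 and 3 and 9 and 8 without SH replicates 1 and 2. The call of TC27189 ended without PAA replicate 3 (adjusted p 0.0564 with limma), where the split was 3 lower and 2 higher. Without SH replicate 3 it was 11 and 10. With normexp by negative controls on 15 arrays the split was 2 lower and 1 higher and the calls of TC27189 and TC27525 ended, as their measured log2 differences fell from 2.79 to 1.72 and from 2.19 to 0.828. That of TC27189 was 3.50 outside the set and 3.40 with arrayWeights. With cyclic loess it was 3 lower and 2 higher, and with median scaling the call of TC16126 ended.

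Averaged over the 3 days, TC22035 was at least 4.14-fold higher under PAA and TC27189 at least 2.04-fold higher, and each was well above background on no SH array and 7 of 8 PAA arrays. TC23205 was at least 2.56-fold lower and well above background on no PAA array. TC23281 (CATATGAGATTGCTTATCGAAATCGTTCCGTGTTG) was at least 3.48-fold lower and well above background on 1 of 8 PAA arrays. Under SH both were so on 7 of 9 arrays. The average is over 8 PAA and 9 SH arrays. In all, 74 probes were lower and 104 higher under PAA, and 169 of these 178 had the same sign on each of the 3 days. The probes were called on the mean of these same 3 differences, which favours 1 sign, so this count says little. An unadjusted p under 0.05 was found for 737 probes, against 600 expected by chance. Of the 178 probes, 39 were also called on day 1, 66 on day 3 and 21 on day 6, and 12 were called on every day. When the 5-array set entered as a block, there were 162 lower and 179 higher, and outside the set 121 and 172. The 15 arrays with their own foreground gave 103 calls with quantile normalization, 88 with normexp by negative controls, 69 with median scaling and 82 with cyclic loess. Normexp ended the calls of TC23205 and TC23281, and moved the measured log2 differences from 3.60 to 2.88 (TC22035), 3.00 to 1.83 (TC27189), -3.02 to -2.04 (TC23205) and -2.79 to -2.17 (TC23281). That of TC22035 was 4.31 outside the set.

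**Figure D2:**
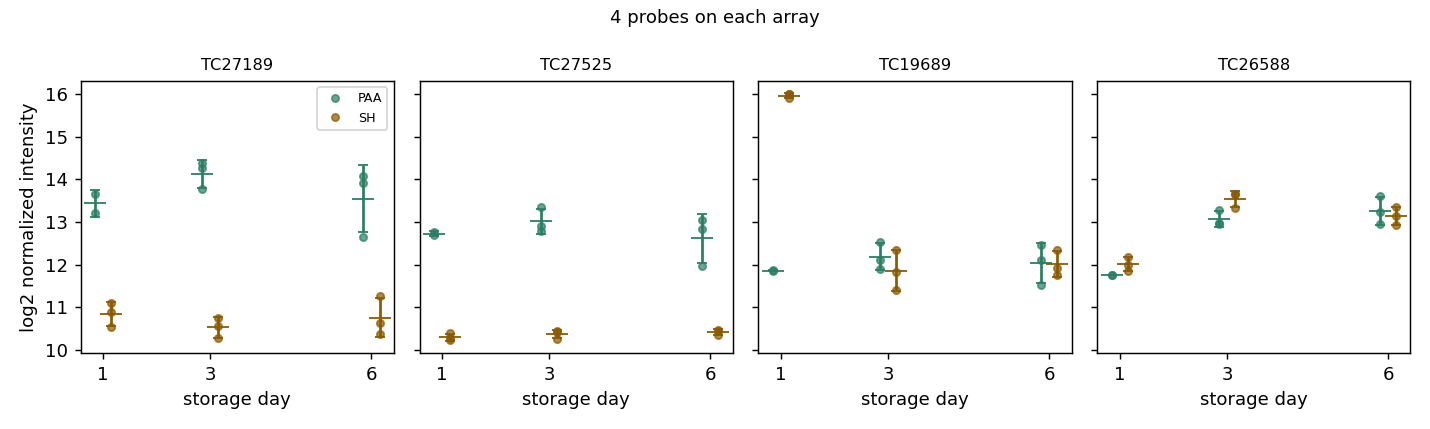
The vertical axis is the log2 normalized intensity and the horizontal axis the storage day; points are single arrays (green PAA, brown SH) and bars are the mean and SD of a group. The measured levels of TC27189 and TC27525 are higher under PAA on all 3 days, TC19689 is high in SH on day 1 only (15.96), and TC26588 is lowest on day 1 under both sanitizers. The SH levels of TC27189 and TC27525 and the day 1 levels of TC26588 are not well above background.

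The second question was how leaves changed during storage under each sanitizer. Under PAA, from day 1 to day 3, TC17639 (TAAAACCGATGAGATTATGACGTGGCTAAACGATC) rose at least 4.29-fold, from a day 1 level not well above background, and TC23507 (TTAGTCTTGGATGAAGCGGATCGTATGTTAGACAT) rose 4.78-fold, well above background on 1 of the 2 day 1 arrays. TC25714 (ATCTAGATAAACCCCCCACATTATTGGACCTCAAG) fell by a measured 6.41-fold (log2 difference -2.68 ± 0.45, SE), which can be too small because 1 of the 2 day 1 arrays was saturated. In all, 18 probes were lower and 20 higher on day 3, with 959 at an unadjusted p under 0.05, against 600 expected by chance. Taking the set of 5 arrays as a block gave 64 lower and 132 higher, and outside the set 40 and 119; no PAA array of day 1 is in the set, so no value within it can be had. The count of 38 was 0 and 24 without day 1 replicates 1 and 2, and 11, 3 and 6 without day 3 replicates 1, 2 and 3. Without day 1 replicate 1 limma called none of TC17639, TC23507 and TC25714. The call of TC25714 ended without any one of the 5 arrays, and that of TC23507 also without day 3 replicate 2. The split was 4 lower and 20 higher without day 1 replicate 2, and 8 and 3 without day 3 replicate 1. The call of TC25714 also ended in all 4 fits of the 15 arrays, and that of TC23507 with median scaling and cyclic loess; normexp moved the log2 difference of TC25714 to -3.32. The split was 9 lower and 3 higher on 15 arrays with quantile normalization, 20 and 12 with normexp by negative controls and 1 and 2 with median scaling.

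From day 1 to day 6 under PAA, TC22800 (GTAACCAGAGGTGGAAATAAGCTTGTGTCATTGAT) fell at least 2.33-fold, from a log2 level of 14.00 ± 0.13 (SD, n = 2). TC16887 (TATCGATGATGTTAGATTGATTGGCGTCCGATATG) fell at least 2.81-fold. Neither was well above background on day 6. TC17287 (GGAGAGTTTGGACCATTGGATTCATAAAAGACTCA) rose by a measured 5.83-fold, which can be too small because 1 of the 3 day 6 arrays was saturated, and TC26588 (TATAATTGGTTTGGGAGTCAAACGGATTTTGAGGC) rose at least 1.54-fold from a day 1 level not well above background. In all, 6 probes were lower and 4 higher on day 6, with 572 at an unadjusted p under 0.05, against 600 expected by chance. Blocking on the set of 5 arrays gave 17 lower and 10 higher, and outside the set 16 and 17. The count of 10 was 2 and 18 without day 1 replicates 1 and 2 and 2 and 4 without day 6 replicates 1 and 3. The calls of TC17287, TC26588 and TC16887 ended without either day 1 array or day 6 replicate 1 (those of TC17287 and TC16887 also without day 6 replicate 3). Without day 1 replicate 2 the split turned to 3 lower and 15 higher, and 2 of the 10 probes were among these. On the 15 arrays the call of TC26588 ended in all 4 fits, that of TC16887 in all but normexp and that of TC17287 with quantile normalization and cyclic loess. The split was 13 lower and 3 higher with normexp by negative controls on 15 arrays, 3 and 0 with quantile normalization and 1 and 0 with cyclic loess.

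Under SH, from day 1 to day 3, TC19689 fell at least 9.71-fold, from 15.96 ± 0.05 (SD, n = 3), where 1 of the 2 day 1 arrays with their own foreground was saturated. TC27339 fell at least 7.63-fold, and neither was well above background on day 3. TC26588 rose at least 1.81-fold from a day 1 level not well above background, and TC19248 (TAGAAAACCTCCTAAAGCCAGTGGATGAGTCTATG) rose 2.63-fold, well above background on 1 of the 3 day 1 arrays. In all, 28 probes were lower and 4 higher on day 3, with 918 at an unadjusted p under 0.05, against 600 expected by chance. The fit with that set as a block gave 106 lower and 68 higher, and outside the set 76 and 48; the pair inside gave log2 differences of -3.55 for TC19689, -3.50 for TC27339, 1.47 for TC26588 and 0.94 for TC19248. The count of 32 fell to 13 without day 1 replicate 1, to 19 without day 3 replicate 1 and to 13 without day 3 replicate 2, and the call of TC19248 ended without any of day 1 replicates 1 and 2 and day 3 replicates 1 and 2. The split was 11 lower and 0 higher with normexp by negative controls on 15 arrays and 5 and 0 with median scaling, and both ended the call of TC26588. That of TC19248 ended in all 4 fits of these arrays and with a trend and robust eBayes. arrayWeights gave 108 lower and 46 higher.

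From day 1 to day 6 under SH, TC27339 fell at least 7.76-fold and TC19689 at least 9.87-fold, with the same saturated day 1 array; neither was well above background on day 6. TC17287 rose 4.23-fold and TC25121 rose 3.55-fold, from 12.90 ± 0.36 (SD, n = 3) to 14.73 ± 0.12 (SD, n = 3), and each was well above background on 2 of the 3 day 1 arrays. In all, 25 probes were lower and 5 higher on day 6, with 699 at an unadjusted p under 0.05, against 600 expected by chance. When the 5-array set entered as a block, there were 85 lower and 53 higher, and outside the set 49 and 34, where TC25121 had an adjusted p of 0.0672 with limma; the pair inside gave log2 differences of -3.93 for TC27339, -3.56 for TC19689, 1.16 for TC17287 and 1.39 for TC25121. The count of 30 was 10 and 17 without day 1 replicates 1 and 2 and 17 and 10 without day 6 replicates 1 and 2, and the call of TC17287 ended without any of these 4 arrays, that of TC25121 without 3 of them. The split was 5 lower and 0 higher with median scaling on 15 arrays, and arrayWeights turned it to 233 lower and 266 higher. In that last fit day 6 replicate 1 had a weight of 7.11, against 0.824 and 0.381 for replicates 2 and 3. On the 15 arrays the call of TC17287 ended in all 4 fits and that of TC25121 with median scaling. In fits of only the groups compared, the calls left among the probes reported here as the highest or lowest of a comparison were those of TC19689 on day 1 and in both SH storage comparisons, TC27189 on day 3, and TC27339 from day 1 to day 3 under SH. The results of TC19689 and TC27339 on day 1, in both SH storage comparisons and in the interaction below rest on the same SH arrays of day 1. They are therefore not separate findings.

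The third question was whether the difference between the sanitizers changed during storage. limma's moderated F-test called 5 probes, and 410 had an unadjusted p under 0.05, against 600 expected by chance. TC19689 (adjusted p 0.00142 with limma), TC27339 and TC19664 (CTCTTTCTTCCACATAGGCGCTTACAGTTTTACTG) were far higher under SH than under PAA on day 1, and none of these 3 was called between the sanitizers on day 3 or day 6. For TC19664 the day 1 difference was at least 6.09-fold, since both SH arrays of that day with their own foreground were saturated, and the log2 difference of PAA from SH was 0.68 ± 0.28 (SE) on day 3, when 2 of the 3 SH arrays were well above background. TC19069 (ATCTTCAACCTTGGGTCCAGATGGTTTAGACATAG) was at least 5.99-fold higher under PAA on day 3, where both PAA arrays with their own foreground were saturated, against log2 differences of 0.53 ± 0.19 (SE) on day 1 and 1.13 ± 0.17 (SE) on day 6, when it was still called (adjusted p 0.0158 with limma). TC25063 (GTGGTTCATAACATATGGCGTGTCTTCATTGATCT) was at least 1.95-fold higher under PAA on day 3. On day 1 it was saturated on both PAA arrays and on 1 of the 2 SH arrays with their own foreground. Its day 1 difference was therefore not measured, and its change between days is not established. As a block, the set of 5 arrays gave 19 called probes, and the fit outside it gave 9, with 2 of the 5 named probes among them. On the 15 arrays, quantile normalization, median scaling and cyclic loess each kept 1 of the 5 and normexp kept 3, as did a trend with robust eBayes. The count of 5 was 1 and 11 without PAA day 1 replicates 1 and 2, 1 without PAA day 3 replicate 1 or 3, 2 without any one SH array of day 1, 2 without SH day 3 replicate 1 and 1 without SH day 3 replicate 2.

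Effects measured on separate arrays were then set side by side across the 12000 probes, which are not independent replicates. The sanitizer differences of days 1 and 3 correlated with Pearson's r = 0.189 and Spearman's rho = -0.0358, those of days 1 and 6 with r = 0.279 and rho = 0.119, and those of days 3 and 6 with r = 0.289 and rho = 0.0403. Blocking on the 5-array set moved the first r to 0.123 and the second to 0.49, and left the last at 0.289. Among called probes, 16 were higher and 8 lower under PAA on both day 1 and day 3, where independent lists would share 0.11 and 0.052. Days 1 and 6 shared 9 higher and 6 lower probes, against 0.0228 and 0.0173, and days 3 and 6 shared 10 and 7, against 0.0682 and 0.016. All 21 probes called on day 6 had the same sign on day 1, and all 21 on day 3. Of the 47 called on day 1, 36 had the same sign on day 3 and 41 on day 6. Of the 87 called on day 3, 68 had it on day 1 and 75 on day 6. The storage changes under PAA and SH correlated with r = 0.248 and rho = 0.242 from day 1 to day 3 and r = 0.392 and rho = 0.408 from day 1 to day 6, and the set block moved the second r to 0.531. From day 1 to day 3, 32 of 38 PAA calls had the same sign under SH and 20 of 32 SH calls under PAA; to day 6 these were 10 of 10 and 25 of 30. The called lists of the 2 sanitizers shared 1 rising and 0 falling probes on day 3, and 2 rising and 3 falling probes on day 6, where independent lists would share 0.00167 and 0.0125. All these lists come from 1 fit with 1 spread per probe, so a probe of small spread is more easily called in each. Some overlap beyond that of independent lists can arise from this alone.

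**Figure D3:**
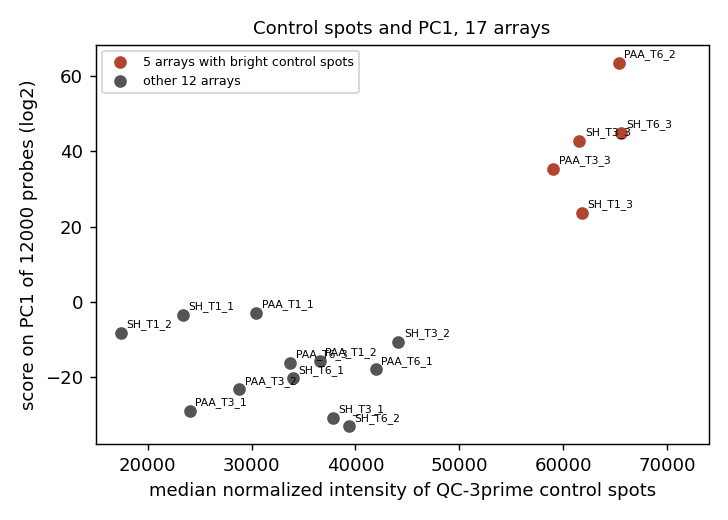
Each point is an array; the horizontal axis is the median normalized intensity of its QC-3prime control spots and the vertical axis its score on the first principal component (PC1) of log2 intensity over 12000 probes. The 5 arrays in red lie at 59069 or more on the control spots and 23.7 or more on PC1, and the other 12 lie at 44143 or less and -2.76 or less.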

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

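The tests of the set of 5 arrays, and those of uneven spots, leaf lots and neighbouring spots, were chosen or changed after the results were seen; the counts over other splits of the arrays were chosen before.

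The sanitizer difference changed between storage days for 5 probes (limma's moderated F-test of the interaction), of which 3 were high in SH on day 1 alone and 1, TC25063, was saturated on day 1, so that its change is not established. The cause was not tested.

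The 178 probes called for the sanitizers averaged over days were set against relabellings of the arrays within days. Of 100 labellings, the real one included, 1 called as many; the highest other called 8, so chance assignment of arrays is excluded at 0.05. For comparisons of 3 arrays against 3 there are 10 splits, too few for a share under 0.05. On day 3 the real split called 87 probes and the highest other 0, and 1 of the 10 splits called as many as the real one. On day 6 the values were 21 and 0, for SH day 3 against day 1 they were 32 and 1, and for SH day 6 against day 1 they were 30 and 0, again with 1 split as large.

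The first pattern weighed is the set of 5 arrays, 1 from each group except PAA on day 1. GC content is argued against, since among the 9987 probes of 40% GC the difference between the sets spread 1.02 times as widely as among all probes. Position on the array is argued against too, since a surface over rows and columns held 2.42% of its variance. Uneven spots are a candidate source: over 10735 probes not saturated on the arrays outside the set, the difference correlated with the ratio of pixel SD to mean there at r = -0.801, which is 64.2% of its variance and not all of it. Over all probes r was -0.753; a log ratio tried first gave -0.358 over all probes and -0.795 over the unsaturated ones, because a saturated spot has a pixel SD of 0. A lot of leaves shared by the 5 arrays stays open, as the labels name no lots and the negative control spots differed by 0.2 in log2 (SE 0.0849), which the prediction left undecided.

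The second pattern is the sanitizer difference averaged over days, for the 178 called probes. Of these, 169 had the same sign on all 3 days, which a call on the average of these days favours, and 12 were called on every day. A trend of each array on spot unevenness is argued against as the whole cause of the pattern. Once this trend was removed, a share of 0.904 of the 178 called probes (161) kept their call. With the log ratio tried first the share was 0.91. All calls together rose to 309 with the removal. It covers only a trend shared by probes of like unevenness, so unevenness particular to single probes was not tested. Light from the next spots along the row is argued against as the source of most of these calls, since a share of 0.542 of 349 such spots moved the same way as the called probe. Such light at a minority of the probes is not excluded, and spots in adjacent rows were not part of this test. Lots of leaves that differed before treatment stay open: the day 6 difference was a median 0.888 times the day 1 difference over 169 probes. These were picked for 1 sign on all 3 days, which favours a ratio near 1, so the ratio decides nothing; a lasting effect of the sanitizers, which the design names, stays open too. Sanitizer and lot cannot be told apart, because the labels name no lots.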

How the results depend on the processing

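The set block, the fit without the set, the unevenness and position corrections and all fits of 15 arrays were chosen after seeing the data. Counts of called probes were 47, 87, 21, 178, 38, 10, 32, 30 and 5, in the order sanitizers on days 1, 3 and 6, their average, PAA days 3 and 6 against day 1, SH days 3 and 6 against day 1, and the interaction. In that order they were 98, 244, 57, 341, 196, 27, 174, 138 and 19 with the set of 5 arrays as a block, 114, 181, 54, 293, 159, 33, 124, 83 and 9 on the other 12 arrays, 124, 215, 57, 309, 120, 48, 137, 122 and 24 with the unevenness trend removed, 127, 216, 57, 316, 131, 50, 152, 129 and 34 with its log ratio, and 145, 311, 138, 402, 260, 26, 154, 499 and 24 with arrayWeights, whose iteration stopped before its tolerance. With position removed they were 78, 151, 23, 233, 52, 14, 66, 51 and 4. The 15 arrays gave 19, 17, 14, 103, 12, 3, 11, 11 and 1 with quantile normalization, 23, 15, 3, 88, 32, 16, 11, 14 and 3 with normexp by negative controls, 5, 13, 5, 69, 3, 2, 5, 5 and 1 with median scaling and 7, 15, 5, 82, 2, 1, 13, 7 and 1 with cyclic loess; the last 3 differ from the 17 arrays in 2 choices. Fits of only the groups compared gave 1, 6, 0, 0, 0, 3 and 2 for the comparisons other than the average and the interaction, with fewer arrays to estimate the spread (for the counts of 0, limma on all 17 arrays had 282, 959 and 572 at an unadjusted p under 0.05). A trend with robust eBayes moved 12 (PAA day 3 against day 1) and 3 (the interaction). The cause of the other changes was not tested. The filter on dim probes left each count within 1.5 times. The authors' deposited table holds the values analysed, so its counts are the same by construction and say nothing about stability.

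In the labels, same-numbered arrays share only a number. Their deviations correlated from -0.743 to 0.858 over 40 pairs, 28 of them above 0.1. The median r was 0.354, against -0.179 for other pairs, and 12 of 17 arrays correlated best with an array of their own number. This is a hint of a tie between same-numbered arrays from the data and not the design, and the main fit does not allow for it. The replicate block gave 45, 100, 23, 192, 15, 6, 43, 32 and 3 calls, over 1.5 times away for 15 (PAA day 3 against day 1), 6 (PAA day 6 against day 1) and 3 (the interaction); for PAA day 6 against day 1 the calls of TC17287 and TC16887 ended. For PAA day 3 against day 1 the split with this block was 10 lower and 5 higher. The set of 5 arrays holds replicate 2 of PAA on day 6 and replicate 3 of the 4 other groups, so the block puts that PAA array apart from the others of the set.

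Leaving out 1 array at a time gave 20 to 37 (sanitizers on day 1), 20 to 72 (day 3), 5 to 36 (day 6), 119 to 198 (their average), 0 to 24 (PAA day 3 against day 1), 2 to 18 (PAA day 6 against day 1), 13 to 38 (SH day 3 against day 1), 10 to 35 (SH day 6 against day 1) and 1 to 11 (the interaction); where this left 1 PAA array on day 1, it was assumed to vary like the other groups. The lowest count of 0 was PAA day 3 against day 1 without PAA day 1 replicate 1. Of 32 results for probes picked by the rule, none reversed over the alternatives run, and 126 of 668 values lost the call. The rule took the largest differences on these same arrays, so the lack of reversals says little about stability.

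With median scaling on 15 arrays the median log2 difference of all probes was -0.124 (sanitizers on day 1) and -0.107 (day 3), against -0.0116 and 0.00713 on 17 arrays. Planned versions of the background, median scaling and cyclic loess on 17 arrays were not run, since 2 arrays have copied foreground columns, nor was a slide or scan block, which no file gives, nor the gene list tests. Signal over background limits dim probes: 30.5% to 49.0% of probes per array were above the 95th percentile of the negative controls.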

Other observations

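From day 3 to day 6 few probes passed the test. Under PAA, limma called 1 lower and 0 higher, with 486 at an unadjusted p under 0.05 against 600 expected by chance. Under SH it called 1 lower and 1 higher, with 154 against the same 600. Whether these numbers differ from those for days 3 and 6 against day 1 was not tested.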
